A study of Mus musculus with 8 samples.

How the data were processed

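Single-cell RNA from Tri-PyMT cells, sorted by fluorescence into RFP+ and GFP+ populations, was measured by Drop-seq with Nextera libraries on an Illumina HiSeq 2500, per the labels' protocols. The reference was GRCm38, per the submitters' processing notes. The deposited table holds raw counts per gene and cell, and its values are whole numbers up to 342. The aligner, the counter, whether molecular identifiers were collapsed and how cells were selected are not given in the sources used here, so values are called counts. The numbers of cells per library (2000, 2000, 1600 and 1800) are round. Column names tell the 4 libraries apart, and each library's 2 lanes, which are separate samples in the labels, stand pooled as one set of cell columns. The library is therefore the replicate.

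Of 16647 gene rows, 772 had no count, 23 had names that look like dates, and 1 row name occurs again and was kept apart. Cells were kept with at least 500 counts and under 20% mitochondrially encoded counts, which left out 10 of 7400 cells, none by the mitochondrial limit. Scrublet, in scanpy 1.11.5, marked 34 cells (0.46%) as doublets. At so low a share the calls were not relied on, no cell was removed as a doublet in the main setting, and the share of doublets is unknown. Libraries of the same population were compared by a chi-square test of their counts over genes. Chi-square per degree of freedom was 1.36 for RFP+ and 1.41 for GFP+ labelled libraries, more than independent counts would give. Counts that are not independent molecules would raise it too, so the test does not show that the libraries are separate. They are taken as separate from the labels. Pearson's r of log2 CPM across 3293 genes was 0.994 to 0.995 within and 0.966 to 0.968 between populations.

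Counts were summed over the cells of each library and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM factors, Benjamini-Hochberg adjustment, threshold 0.05), with 2 libraries per population and no covariate. Genes were tested with at least 10 CPM (counts scaled to a common library total) in either population and at least 20 counts in all, which left 7596. The common biological coefficient of variation was 0.035. Values per population are means ± SD of 2 libraries and log2 folds are given ± SE. That SE is the absolute log2 fold over the square root of the F statistic. It rests on a dispersion moderated across genes, with a median of 39.25 prior degrees of freedom. The SE is thus not a gene's own spread between libraries. On simulated libraries with known answers for this comparison (7468 genes tested), 98.0% of genes changed 2-fold and 62.2% of those changed 1.5-fold were recovered, and 11 of 169 calls were of unchanged genes. Every simulated gene had the common dispersion fitted to these libraries. The rates therefore hold under that model and do not show the rate of false calls in the real counts. The main design, the tests, the rule for naming genes and the 26 gene lists were fixed before the data were examined.

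The lists cover epithelial, mesenchymal, mammary luminal and basal genes, transition factors, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, G1/S, G2/M, glycolysis and hypoxia, interferon response, class I presentation, TGF-beta targets, chemokines and cytokines, p53 targets, unfolded protein and integrated stress, dissociation and heat stress, cholesterol synthesis, drug and aldehyde metabolism, reporters, and immune, endothelial, fibroblast and erythroid markers. Lists with enough tested genes, 21 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation as an alternative, and with fry. With an estimated correlation, camera also takes its degrees of freedom from the few libraries instead of the many genes. That raises p apart from the correlation itself. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. Genes named are a fixed set of markers, the 12 largest changes per direction among called genes with at least 100 CPM in the higher population (leaving out gene models, mitochondrially encoded and ribosomal protein genes), and per list the 4 largest changes among members with at least 50 CPM. Genes named outside this rule are said to be so. Not every gene that the rule names is reported here. Coordinates, lengths and GC content come from GENCODE M21 on GRCm38, and 95.4% of tested genes had a length. Length and GC content are those of a gene's longest protein-coding transcript, or of its longest transcript where none is protein-coding.

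For shares of cells each cell was thinned to 1000 counts and shallower cells were left out. Intervals are exact Clopper-Pearson at 95%. The axis is log2 of a cell's mesenchymal counts plus 0.5, less log2 of its epithelial counts plus 0.5, cut into 5 equal bins within each population. Genes on the axis were left out of the lists read along it. Random lists for the axis, 1000 per list, drew for each gene a stand-in from the 40 genes nearest to it in total counts. Axis genes could not be drawn, but other members of the same list could. Clusters used counts per 10000 on a log scale, 2000 variable genes, 20 principal components, 15 neighbours and Leiden at a resolution of 0.5.

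Alternatives were other scalings (DESeq2 1.42.0 size factors, plain totals), filters of 1 count and 50 CPM, other cell filters, cells weighted equally or thinned, totals without mitochondrial and ribosomal protein genes, doublet calls left out, DESeq2's Wald test, each library left out, other set tests, and other settings for shares, axis and clusters. Length and GC offsets (loess, span 0.5) were added after the data were seen. Lanes could not be treated as samples and no replicate number could be used as a block, because the columns merge lanes.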

Results

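Tri-PyMT cells are a mouse mammary tumour line from an animal with the MMTV-PyMT oncogene, an Fsp1-cre transgene and the Rosa26mT/mG reporter. The reporter makes a red membrane protein (RFP) until the Cre recombinase cuts out its cassette, and a green one (GFP) from then on. Cre is driven here by the promoter of Fsp1, another name for S100a4, a gene of fibroblasts and of cells that have left the epithelial state. Cultured cells were sorted into RFP+ and GFP+ populations, and single cells were profiled by Drop-seq, in which a cell and a barcoded bead share a droplet and polyadenylated RNA is counted per barcode. The labels list 8 samples, 4 per population, which are 2 libraries per population on 2 lanes each, so n is 2 libraries per population throughout. The count table held 7400 cells and 16647 gene rows, and 7390 cells with at least 500 counts were used. The libraries labelled RFP+ held 3081009 counts from 1998 cells and 2988631 counts from 1997 cells. Those labelled GFP+ held 2598187 counts from 1597 cells and 2550319 counts from 1798 cells. Median counts per cell were 1235 and 1224 in the libraries labelled RFP+ and 1358 and 1166 in those labelled GFP+. Nothing in the labels says that the libraries of a population came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

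The rows for the reporter transcripts went against the labels. CUSTOM_GFP was at 612 and 590 CPM (counts scaled to a common library total) in the libraries labelled RFP+ and at 99.7 and 104 in those labelled GFP+, a log2 fold of -2.57 ± 0.070 (SE) of GFP+ over RFP+ labelled libraries. CUSTOM_RFP was at 132 and 137 CPM in the libraries labelled RFP+ and at 2943 and 3053 in those labelled GFP+, a log2 fold of 4.47 ± 0.062. The edgeR adjusted p was 1.62e-29 for CUSTOM_GFP and 5.35e-41 for CUSTOM_RFP. S100a4, whose promoter drives the recombinase, was at 662 ± 20.3 CPM (SD, n = 2) in the libraries labelled RFP+ and 1979 ± 191 in those labelled GFP+. Every direction given here is therefore that of the libraries as labelled, and the reporter rows do not bear the labels out.

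**Figure D1:**
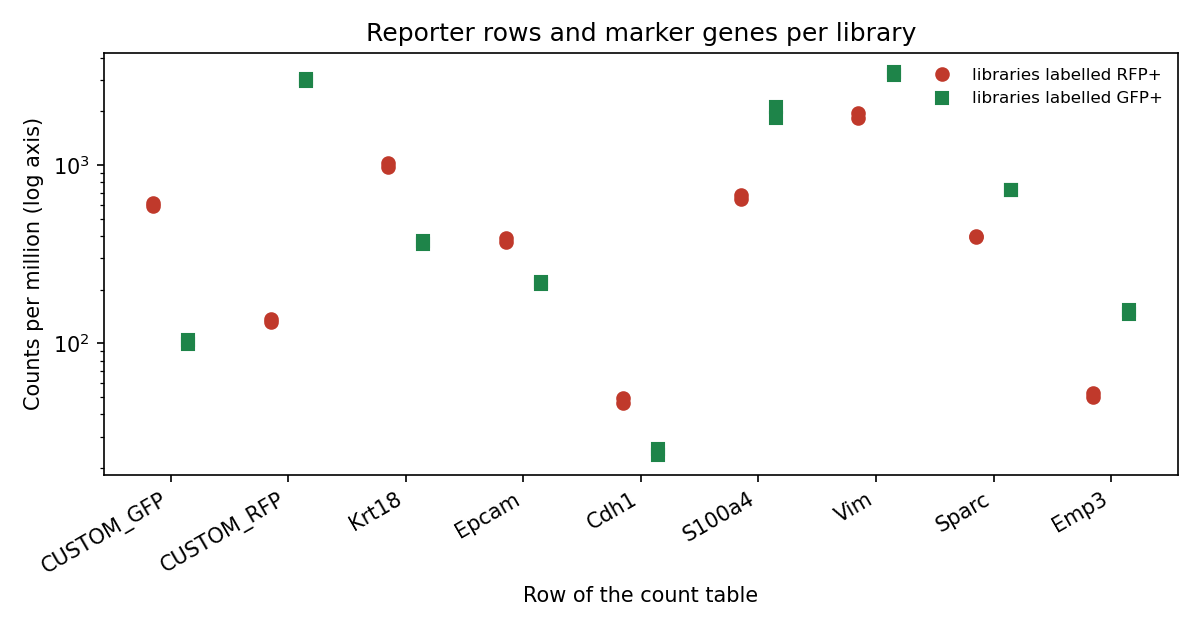
CPM (log axis) of both reporter rows and 7 marker genes, with 1 point per library, circles for libraries labelled RFP+ and squares for those labelled GFP+. CUSTOM_RFP lies at 2943 and 3053 in the libraries labelled GFP+, and Krt18 falls from 998 to 367 on average while S100a4 rises from 662 to 1979.

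The main comparison asked how transcription differs between cells sorted by whether the Fsp1-cre reporter had switched. The libraries labelled GFP+ had lower Krt18, Krt8, Krt7, Krt14 and Cldn3 and higher S100a4, Emp3, Vim and Sparc. Krt18, a keratin of simple epithelia, fell from 998 ± 31.3 to 367 ± 9.49 CPM (SD, n = 2). Vim, the intermediate filament protein of mesenchymal cells, rose from 1892 ± 77.9 to 3251 ± 90.5 CPM. Of 7596 genes tested with edgeR, 1189 were higher and 1126 lower in the libraries labelled GFP+ at an adjusted p under 0.05. Differences were mostly small: 374 of the higher and 380 of the lower genes reached 1.5-fold, and 90 and 102 reached 2-fold. DESeq2's Wald test called 364 genes higher and 370 lower, and edgeR on cells thinned to 1000 counts called 737 and 727.

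Among called genes with at least 100 CPM, the largest rises after CUSTOM_RFP included those of S100a4, Emp3, Sema3a, Prkg2, Mgp, Ftl1, Dst, Hist1h2ae, Map1b and Sh3kbp1. S100a4 (GRCm38 chromosome 3, 90603771 to 90606045) rose by a log2 fold of 1.57 ± 0.057 with an edgeR adjusted p of 1.26e-24. Emp3, a small membrane protein gene on chromosome 7 (45918023 to 45921404), rose from 51.4 ± 2.16 to 150 ± 5.99 CPM, a log2 fold of 1.53. Sema3a, a secreted semaphorin that steers axons, reached 102 ± 9.86 CPM with the same log2 fold. Prkg2, a cGMP-dependent kinase, had a log2 fold of 1.31, and Mgp, the matrix Gla protein, one of 1.12. Map1b, which encodes a large protein that binds microtubules, had a log2 fold of 0.98. Ftl1 and Hist1h2ae have near-identical copies or pseudogenes in the mouse genome and are uncertain.

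Among called genes with at least 100 CPM, leaving out mitochondrially encoded genes, ribosomal protein genes and gene models, the largest falls after CUSTOM_GFP were those of Krt18, Krt14, Krt7, Tpd52l1, Krt8, Tmem176b, Wfdc2, Rnaset2a, Ubald2, Cystm1 and Tagln2. Krt18 (chromosome 15, 102028180 to 102032027) had a log2 fold of -1.46 ± 0.057 with an edgeR adjusted p of 1.03e-23. Its partner Krt8 (chromosome 15, 101996698 to 102004482) fell from 425 ± 8.33 to 171 ± 23.3 CPM, a log2 fold of -1.33. Krt14, a keratin of basal cells, fell from 111 ± 21.3 to 42.5 ± 5.21 CPM. Wfdc2, a secreted protein of glandular epithelia, fell from 1043 ± 13.0 to 503 ± 21.1 CPM. Tagln2, an actin-binding protein gene, fell by 0.94 on the log2 scale.

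Epithelial genes fell together. Of 39 tested members of the epithelial list, 32 fell, none rose and 7 did not pass, and adjusted over the list alone 34 fell and 1 rose. The list's median log2 fold was -0.98, with a camera adjusted p of 5.21e-32 over 21 lists and an adjusted p of 0.125 with an estimated correlation. Cldn3, a tight junction claudin, fell from 68.9 ± 7.54 to 9.90 ± 0.694 CPM, a log2 fold of -2.81 ± 0.18. Lcn2, a secreted iron-siderophore binder, fell by 2.15 on the log2 scale, and Krt7 by 1.35. Among adhesion genes, Epcam (chromosome 17, 87635979 to 87651129) fell from 381 ± 11.7 to 218 ± 5.10 CPM and Cdh1 (chromosome 8, 106603351 to 106670246), which encodes E-cadherin, from 47.6 ± 2.19 to 24.5 ± 1.33. Summed over the list, epithelial transcripts were at 5325 ± 12.6 CPM in the libraries labelled RFP+ and 2819 ± 127 in those labelled GFP+, a ratio of 0.529. Of the 8 tested genes of the mammary luminal list, which shares Krt8, Krt18, Krt19 and Lcn2 with the epithelial list, 6 fell and none rose, also when adjusted over the list alone. Its median was -1.08, with a camera adjusted p of 2.22e-17 and an adjusted p of 0.125 with an estimated correlation. The mammary basal list had 4 tested genes, of which 2 fell and 1 rose, also when adjusted over the list alone, with a median of -0.43 and a camera adjusted p of 0.111. Without library 1 labelled RFP+ that p was 0.0177, and without library 1 labelled GFP+ the median was 0.04.

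Mesenchymal genes rose, with exceptions. Of 38 tested members of the mesenchymal list, 21 rose, 3 fell and 14 did not pass, and adjusted over the list alone 21 rose and 4 fell. The median log2 fold was 0.38, with a camera adjusted p of 1.7e-14 and an adjusted p of 0.153 with an estimated correlation. Vim (chromosome 2, 13573927 to 13582826) had a log2 fold of 0.77 ± 0.049, Sparc, a matrix glycoprotein, 0.86 ± 0.056, and Cdh2, which encodes N-cadherin, 0.86 ± 0.10. Fn1 (fibronectin, chromosome 1, 71585520 to 71653200) rose from 97.8 ± 2.09 to 129 ± 6.82 CPM, a log2 fold of 0.38, with an edgeR adjusted p of 0.000982. With length and GC offsets its log2 fold was 0.21 (adjusted p = 0.0778), and DESeq2's Wald test did not call it. The members that fell were Igfbp7, Axl and Timp3, which were named after their values were seen. Col1a1 and Col3a1, fibrillar collagens, were too low to test: Col1a1 had 0 and 0 counts in the libraries labelled RFP+ and 1 and 4 in those labelled GFP+, and Col3a1 had 2 and 1 against 13 and 8. Col1a2, another fibrillar collagen on the mesenchymal list and also named after its values were seen, rose from 2.29 ± 1.35 to 39.9 ± 6.29 CPM, a log2 fold of 4.07.

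**Figure D2:**
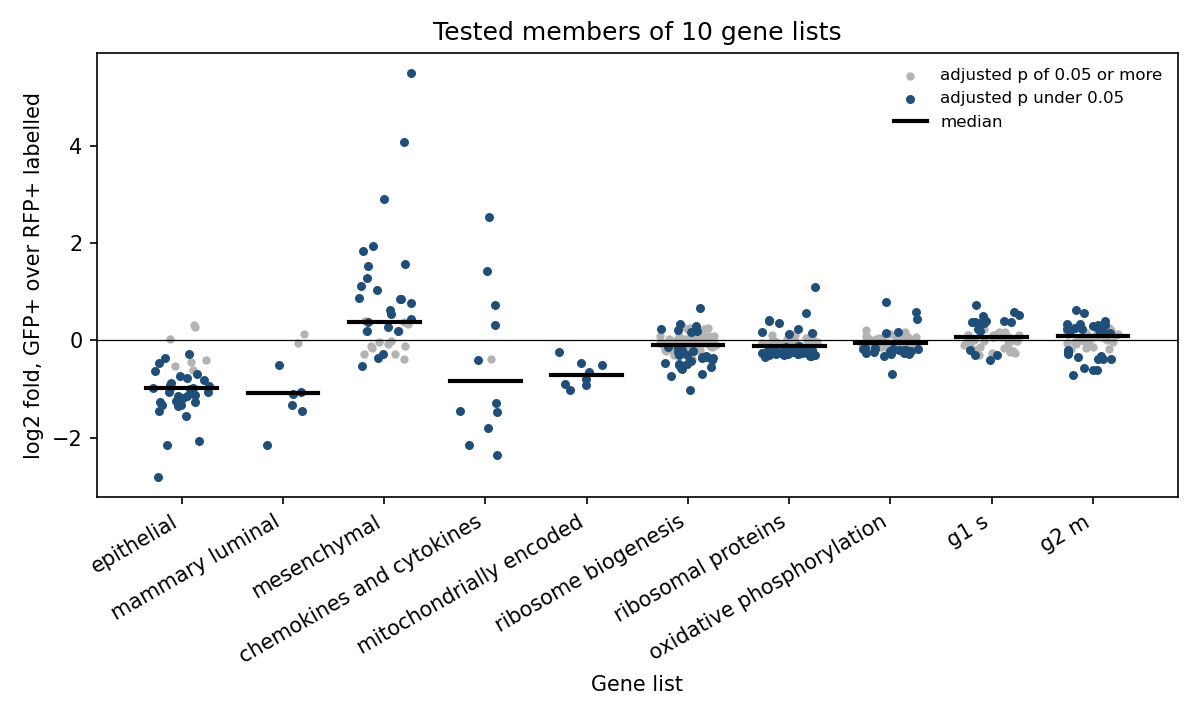
Log2 fold of GFP+ over RFP+ labelled libraries for each tested member of 10 gene lists, with 1 point per gene, dark where the edgeR adjusted p was under 0.05, and a bar at the median. The epithelial list has a median of -0.98 and the mesenchymal list one of 0.38, while the medians of the ribosome biogenesis and cell cycle lists lie between -0.09 and 0.08.

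Transcription factors linked to the epithelial to mesenchymal transition moved both ways. Of 12 tested, 5 rose and 2 fell, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.675). Zeb1 and Zeb2, repressors of Cdh1, had log2 folds of 0.62 ± 0.19 and 0.55 ± 0.16, and Snai1, another such repressor, 0.85 ± 0.25, at levels of 16.5 to 37.5 CPM in the libraries labelled GFP+. These calls depended on single libraries and on the setting. Without library 2 labelled GFP+ the log2 fold of Zeb1 was 0.44 with an edgeR adjusted p of 0.167, and that of Zeb2 0.44 with 0.0899. Snai1 lost its call without library 1 labelled RFP+ (adjusted p = 0.104) and without library 1 labelled GFP+ (adjusted p = 0.101). With length and GC offsets the log2 fold of Zeb1 was 0.45 (adjusted p = 0.0708) and that of Zeb2 0.30 (adjusted p = 0.166), and 2 members of the list rose instead of 5. In thinned cells Zeb1 and Snai1 had adjusted p values of 0.216 and 0.229, and in cells with at least 1000 counts Zeb1 had one of 0.0738. DESeq2's Wald test called none of Zeb1, Zeb2, Snai1 and Hmga2. Hmga2, a chromatin protein, rose by a log2 fold of 0.48, while Sox9 and Sox4 fell by 0.64 and 0.41. Twist1 had a log2 fold of -0.39 ± 0.23 with an adjusted p of 0.199. Snai2 was under the level tested, at 8.07 ± 0.059 CPM in the libraries labelled RFP+ and 8.16 ± 0.107 in those labelled GFP+.

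Ribosome biogenesis genes were slightly lower in the libraries labelled GFP+, and cell cycle genes moved both ways. Of 105 ribosome biogenesis genes tested, 25 fell, 7 rose and 73 did not pass, with the same counts when adjusted over the list alone. The median log2 fold was -0.09, with a camera adjusted p of 0.0135 and an adjusted p of 0.235 with an estimated correlation. Eif6, a factor that keeps the large subunit apart until it is mature, fell from 424 ± 12.9 to 257 ± 8.43 CPM. Fbl, the methyltransferase fibrillarin, fell by 0.43 on the log2 scale and Npm1, a nucleolar chaperone, by 0.22. Ncl, the nucleolin gene (chromosome 1, 86344719 to 86359400), had a log2 fold of -0.11 ± 0.046 with an edgeR adjusted p of 0.0627. With length and GC offsets Ncl was at -0.34 (edgeR adjusted p = 1.04e-08). The length taken for Ncl was 8202 bases, and no other transcript was tried, so this value depends on that choice. Ncl also passed without a filter (0.0446) and in cells with at least 1000 counts (0.0433). Of 50 G1/S genes, 13 rose and 4 fell (camera adjusted p = 0.468), and of 59 G2/M genes, 15 rose and 12 fell (camera adjusted p = 0.523). Adjusted over each list alone, 13 G1/S genes rose and 5 fell, and 16 G2/M genes rose and 12 fell. With length and GC offsets 11 G1/S genes rose and 7 fell, and 8 G2/M genes rose and 9 fell. Mki67, the proliferation marker Ki-67, rose from 358 ± 12.6 to 557 ± 19.0 CPM, a log2 fold of 0.62, and Dlgap5, a spindle protein, by 0.56. Cdc20 and Ube2c, which drive destruction of mitotic cyclins, fell by 0.60 and 0.58. Top2a had a log2 fold of 0.19 with an adjusted p of 0.00697, which without library 2 labelled RFP+ was 0.114. With the offsets Top2a was at 0.05 (adjusted p = 0.545), and DESeq2's Wald test did not call it.

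Mitochondrially encoded transcripts fell. All 8 tested fell, also when adjusted over the list alone, with a median log2 fold of -0.72, a camera adjusted p of 2.27e-15 and an adjusted p of 0.153 with an estimated correlation. mt-Nd1, a subunit of complex I, fell from 393 ± 4.82 to 194 ± 1.73 CPM. All mitochondrially encoded rows together were 0.664% and 0.644% of counts in the libraries labelled RFP+ and 0.403% and 0.378% in those labelled GFP+. Of 77 cytosolic ribosomal protein genes, 37 fell and 9 rose, or 42 and 9 when adjusted over the list alone. Their median was -0.12, with a camera adjusted p of 0.000237 and an adjusted p of 0.54 with an estimated correlation. Of 76 nuclear oxidative phosphorylation genes, 18 fell and 5 rose, also when adjusted over the list alone, with a median of -0.06 and a camera adjusted p of 0.0785, which was 0.0409 without library 2 labelled GFP+ and 0.00289 without a filter. Under fry the ribosomal protein list had an adjusted p of 0.129.

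The fold between populations followed transcript length. Spearman's rho across 7244 tested genes with a GENCODE length was 0.36 for length and -0.26 for GC content, and genes are not independent replicates. Median log2 folds over 5 bins of genes from short to long were -0.16, -0.08, 0.01, 0.10 and 0.21. Between libraries of the same population rho with length was -0.038 and -0.043. With length and GC offsets in the edgeR fit, a setting chosen after this trend was seen, the medians of the ribosomal protein and oxidative phosphorylation lists turned to 0.086 and 0.12. The camera adjusted p values were then 0.014 and 0.00284 in the higher direction, at the preset correlation. An estimated correlation was used only without offsets, where camera gave these lists adjusted p values of 0.54 and 0.586. With the offsets the epithelial list stayed at -0.95, the mesenchymal list at 0.33, the mitochondrially encoded list at -0.58 and the ribosome biogenesis list at -0.073. Some genes named by rule kept their call while the offsets shrank their log2 fold by a factor over 1.5. They include Mki67 (to 0.35), Dst (0.58), Fbl (-0.20), Npm1 (-0.12), Bax (-0.41), H2-K1 (-0.34), Ifitm3 (-0.16) and Junb (-0.49). Gar1 (-0.34), Mrto4 (-0.37), Psme1 (-0.29) and Ifi27 (-0.28) are also among them. The log2 fold of Igfbp7, named after its values were seen, moved from -0.54 to -0.28.

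**Figure D3:**
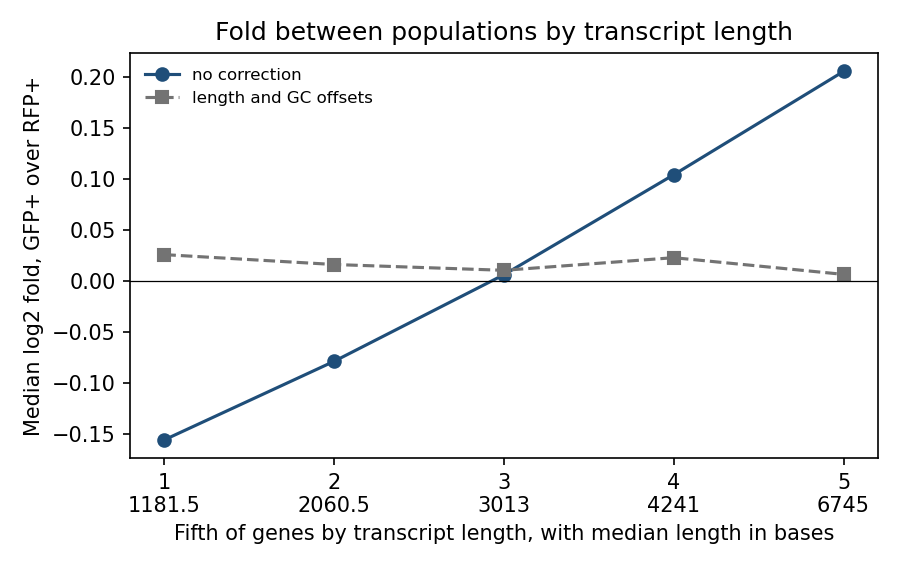
Median log2 fold of GFP+ over RFP+ labelled libraries in 5 bins of the tested genes by transcript length, circles without and squares with length and GC offsets. Without offsets the median goes from -0.16 in the shortest bin to 0.21 in the longest, and with offsets all 5 medians lie between 0.01 and 0.03.

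Secreted signals differed by gene. Of 12 chemokine and cytokine genes tested, 7 fell, 4 rose and 1 did not pass, with the same counts when adjusted over the list alone. The median log2 fold was -0.85, with a camera adjusted p of 0.00591 and an adjusted p of 0.282 with an estimated correlation. Ccl5, which attracts T cells, fell from 80.4 ± 3.40 to 15.8 ± 9.27 CPM, and Cxcl16 from 99.0 ± 1.90 to 35.9 ± 2.55. Lcn2 is on this list too. The list's median was -0.52 without library 1 labelled RFP+ and -0.37 without library 1 labelled GFP+, with camera adjusted p values of 0.0033 and 0.0479. Cxcl12, the ligand of Cxcr4, rose from 36.8 ± 11.8 to 100 ± 4.45 CPM, a log2 fold of 1.42. Of 20 interferon response genes, 6 fell and 2 rose (camera adjusted p = 0.0779), among them Ly6e, which fell by 0.56, and Ifitm3, which fell by 0.36. That p was 0.0422 without library 2 labelled RFP+ 0.0343 without library 2 labelled GFP+, 0.00371 with a filter of 50 CPM and 0.00841 without a filter. Of 13 genes of class I antigen presentation, 6 fell and 3 rose (camera adjusted p = 0.25, fry adjusted p = 0.0151), with H2-K1, a class I heavy chain whose family members share sequence, at -0.54 and Tapbp, or tapasin, at -0.78. Adjusted over each list alone, 7 interferon response genes fell and 2 rose, and the counts for antigen presentation were the same. With length and GC offsets 4 antigen presentation genes fell and 4 rose, and 6 interferon response genes fell and 1 rose.

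Of 19 p53 targets, 5 fell and 1 rose, or 6 and 1 when adjusted over the list alone, with a median of -0.28, a camera adjusted p of 0.0232 and an adjusted p of 0.314 with an estimated correlation. Those that fell include Perp and, named after its value was seen, Sfn, which are both on the epithelial list too, and Bax, a pore-forming protein of apoptosis, which fell by 0.71. DESeq2's Wald test did not call Perp. Cdkn1a, the p53-induced cell cycle inhibitor, had a log2 fold of -0.26 with an edgeR adjusted p of 0.0865. Without library 1 labelled RFP+ its log2 fold was -0.40. The camera adjusted p of this list was 0.0513 without library 2 labelled GFP+, 0.0585 with length and GC offsets, 0.0942 with thinned cells and 0.358 with a filter of 50 CPM.

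The other lists did not pass in the main setting. Of 25 cholesterol synthesis genes, 8 rose and 1 fell (camera adjusted p = 0.0978), with Cyp51, a demethylase of the pathway, at 0.56 and Sqle, squalene epoxidase, at 0.40. The cholesterol list's p was 0.0346 without library 1 labelled RFP+, 0.0343 with cells weighted equally and 0.0182 without a filter. Sqle lost its call in thinned cells (adjusted p = 0.0845) and under DESeq2's Wald test. Of 30 genes of drug efflux and aldehyde metabolism, 8 rose and 4 fell (camera adjusted p = 0.468). Abcg2, a drug efflux pump, rose from 49.7 ± 3.59 to 84.5 ± 0.287 CPM and Gstp1, a glutathione transferase with close copies, by a log2 fold of 0.82. The multidrug pump gene Abcb1b was at 32.3 ± 0.695 and 32.7 ± 4.28 CPM, and Abcb1a had 2 and 1 counts against 1 and 0. Aldh1a1 had 0 counts in all 4 libraries, where 3 counts are the limit that a count of 0 allows, and Aldh1a3 had 6 and 13 against 7 and 8. Of 28 glycolysis and hypoxia genes, 8 rose and 7 fell (camera adjusted p = 0.91), with Hk1, hexokinase, at 0.83 and Mif at -0.41, or at -0.10 (adjusted p = 0.162) with length and GC offsets. The list's median was -0.08 and its mean 0.04. Of 20 TGF-beta targets, 2 rose and 5 fell (camera adjusted p = 0.322), of 31 genes of the unfolded protein and integrated stress responses 8 rose and 12 fell (0.666), and of 24 dissociation and heat stress genes 6 rose and 10 fell (0.523). The median of the unfolded protein list was 0.03 and its mean -0.12. Junb, an immediate early factor, had a log2 fold of -0.74 and Fos one of 0.49. Adjusted over each list alone, 9 genes rose and 5 fell for drug efflux, 8 and 8 for glycolysis and 8 and 14 for the unfolded protein response, and the counts for cholesterol synthesis, TGF-beta targets and heat stress were the same. With length and GC offsets, 7 glycolysis genes rose and 2 fell (camera adjusted p = 0.337), and 7 heat stress genes rose and 4 fell (0.92).

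Summed CPM of the immune list were 49.5 ± 4.79 in the libraries labelled RFP+ and 26.4 ± 3.09 in those labelled GFP+, and those of the endothelial list 40.7 ± 1.69 and 51.0 ± 6.20. The fibroblast list was at 12.5 ± 3.46 and 67.6 ± 7.48 CPM, of which Col1a2, also on the mesenchymal list, made up 2.29 and 39.9. The erythroid list had 1 count in 1 library and 0 in the other 3. Of the genes of these lists that could be tested, S100a8 fell, Flt1, Col1a2 and Pdgfrb rose, and Ly6c1 did not pass, all named after their values were seen.

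The next comparison asked how many cells carried epithelial and mesenchymal transcripts at once. With every cell thinned to 1000 counts, 31.0% of the cells of the libraries labelled RFP+ (919 of 2968) and 19.0% of those labelled GFP+ (503 of 2652) had at least 1 count of Epcam or Cdh1. Per library the shares were 29.8% and 32.2% against 18.7% and 19.3%, with exact 95% binomial intervals of 27.6 to 32.2% and 29.8 to 34.7%, and of 16.7 to 20.8% and 17.1 to 21.6%, which cover counting error only. Vim was seen in 79.2% and 77.0% of cells against 92.2% and 92.8%. Both were seen in 22.1% of cells of the libraries labelled RFP+, where independence would give 24.2%, and in 16.1% of those labelled GFP+, where it would give 17.5%. Thinning left out 1027 and 743 shallower cells, and without it the shares were 39.3% and 25.6% with Epcam or Cdh1, 85.1% and 95.6% with Vim, and 32.9% and 23.8% with both. With 2 libraries against 2, an exact two-sided permutation test cannot give a p under 0.333. No cell type that should lack these genes was found among the cells, so the share that free RNA gives is unknown.

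Ribosome biogenesis transcripts were also followed along an axis from epithelial to mesenchymal within each population. Over 5 equal bins of cells, from the most epithelial to the most mesenchymal, their share went from 262 to 234 counts per 10000 in the libraries labelled RFP+ and from 254 to 226 in those labelled GFP+. These are changes of -10.1% and -10.7% in the libraries labelled RFP+ and of -11.2% and -10.5% in those labelled GFP+. The share is a sum over the list, so its most abundant genes weigh most, and single genes were not followed along the axis. Over both libraries labelled RFP+ together the bins were at 262, 248, 243, 237 and 234, while in library 2 alone bin 4, at 238.6, was not below bin 3, at 238.1. In those labelled GFP+ the difference lay between bins 1 and 2, at 254 and 222, and the last 3 bins were at 223, 219 and 226. Bin 1 also held the cells with the highest median counts before thinning. In the libraries labelled RFP+ it was at 1545.5, against 1360 to 1410 in the other bins. In those labelled GFP+ it was at 1474, against 1358 to 1441. Whether the share goes with counts per cell was not tested. In both populations the log2 ratio of the last to the first bin, -0.16 and -0.17, was under that of all 1000 random lists matched on total counts, a comparison chosen after the values were seen. By the same comparison the G2/M list lay at percentiles 98.8 and 96.8 of its random lists, the ribosomal protein list at 27.4 and 1.2, and the G1/S list at 81.9 and 31.9 (RFP+ and GFP+ labelled libraries). Stand-ins were drawn gene by gene and were not matched on length or on how a list's genes vary together. The random lists may therefore spread too little, and these positions may overstate how unusual a list is. Other members of a list could also be drawn as stand-ins. Ribosomal protein genes held 16.2% to 17.9% of counts, so their random lists may hold many of the same genes. The positions of that list therefore tell little. Ribosomal protein genes may also stand in for Ncl and Npm1, which are abundant. The G2/M share went from 117 to 122 and from 125 to 130 per 10000, and the G1/S share from 66.9 to 67.2 and from 69.8 to 67.9. The G2/M log2 ratio of 0.05 in both populations changed sign in the libraries labelled RFP+ without thinning (-0.02) and in those labelled GFP+ with few genes on the axis (-0.02). A bin is a range of a score, not a cell type, and no test was made from cells. The axis had an SD of 1.17 and 1.17 in the libraries labelled RFP+ and of 1.36 and 1.29 in those labelled GFP+. Counting noise alone, drawn from each library's mean, gave 0.762 and 0.736, and 0.942 and 0.936. A cell's bin is therefore partly set by counting noise.

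**Figure D4:**
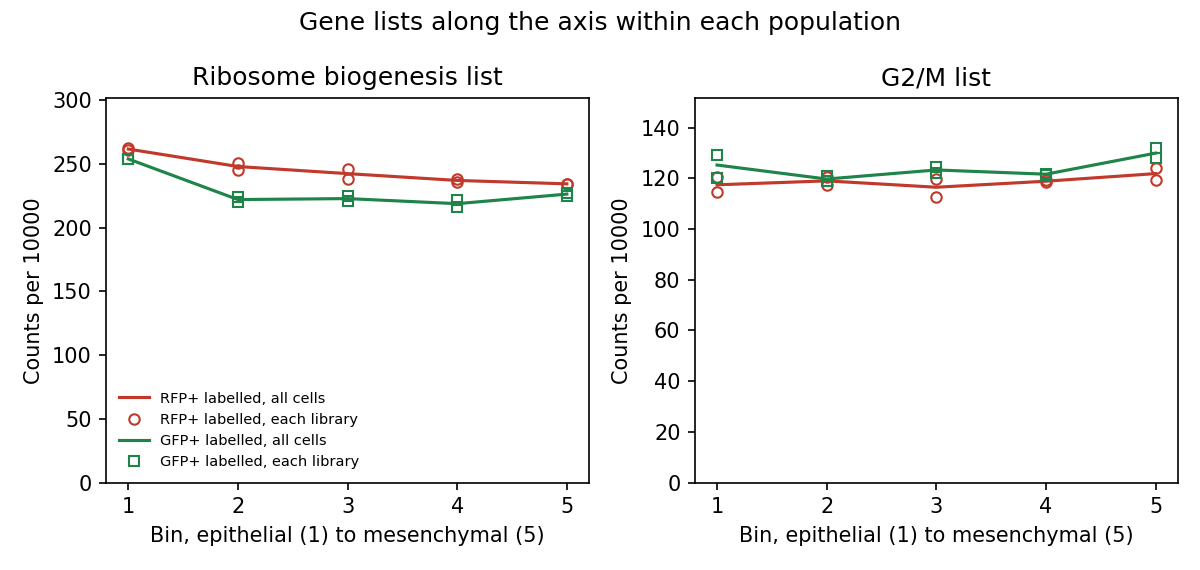
Counts per 10000 of the ribosome biogenesis list (left) and the G2/M list (right) in 5 equal bins of cells along the epithelial to mesenchymal axis, with lines for all cells of a population and open symbols for each library. The ribosome biogenesis share goes from 262 to 234 in the libraries labelled RFP+ and from 254 to 226 in those labelled GFP+.

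Clustering gave 3 clusters of 2763, 1844 and 2783 cells, and other settings gave 2 to 7, with adjusted Rand indices to these 3 of 0.36 to 0.647. The cluster of 2783 cells was epithelial-like by the markers fixed beforehand, with Cldn3, Lcn2, Krt7 and Krt8 among its 10 leading genes, beside CUSTOM_GFP and mt-Nd1. The cluster of 1844 cells, led by CUSTOM_RFP and S100a4, and that of 2763 cells, led by mitotic and long genes such as Aspm and Cenpf and with a median of 1681 counts per cell, had none of the markers among their 10 leading genes and stay unnamed. The leading genes differ between the populations, so cluster sizes are not compared.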

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

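Length and GC offsets were chosen after the data were seen, and the other alternatives before. Over 21 lists and 357 comparisons with an alternative, 318 kept direction and call, 13 lost the call, 11 gained it and 15 changed sign, and of 1706 such comparisons for 107 named genes, 1637, 57, 4 and 8 did. Of these sign changes, 21 were between values not called under either setting, and the others are those of the ribosomal protein list, called under both, and the oxidative phosphorylation list, called with the offsets. DESeq2's Wald test called 364 genes higher and 370 lower, and thinned cells gave 737 and 727, where fewer counts were used. The other alternatives gave 835 to 1247 higher and 817 to 1166 lower genes. Without a library, 871 to 929 genes were higher and 797 to 920 lower, and the lone library is then assumed to vary like the pair. With an estimated correlation the epithelial list (median -0.98) had an adjusted p of 0.125, the mesenchymal list (0.38) one of 0.153 and the ribosome biogenesis list (-0.091) one of 0.235. Without each library in turn their medians ranged from -1.02 to -0.93, from 0.33 to 0.45 and from -0.12 to -0.08. With the offsets the medians were 0.12 for oxidative phosphorylation, 0.086 for ribosomal proteins, -0.040 for the unfolded protein list and -0.11 for Abcb1b. A filter of 50 CPM gave -0.24 for transition factors, 0.14 for glycolysis and 0.046 for TGF-beta targets, where fewer genes were tested. Without a filter the medians were -0.0004 for drug metabolism and -0.20 for the unfolded protein list, and Abcb1b was at -0.0004. The unfolded protein list was at -0.057 in cells with at least 1000 counts, at -0.072 thinned and from -0.081 to 0.039 without each library in turn, cholesterol synthesis at -0.0057 thinned, and the mammary basal list from -0.59 to 0.042, the latter without library 1 labelled GFP+. Abcb1b was at -0.0020 with DESeq2 size factors, -0.0026 in cells with at least 1000 counts, -0.0049 with doublet calls left out, -0.0012 under the Wald test, and from -0.15 to 0.14 without each library in turn. Shares of cells with Epcam or Cdh1 were 39.3% and 25.6% (RFP+ and GFP+ labelled libraries) unthinned, 47.4% and 33.2% thinned to 2000 counts, and 9.10% and 3.88% with at least 2 counts. With Vim as well they were 32.9% and 23.8%, 40.6% and 32.3%, and 3.50% and 1.85%. With at least 2 counts of the whole epithelial list they were 90.4% and 67.6%, and with 2 of the mesenchymal list as well 90.4% and 67.5%, where the mesenchymal list alone was met by 2968 of 2968 and 2651 of 2652 cells. These moves follow from the depth and from what is counted. The ribosome biogenesis log2 ratio along the axis was -0.12 and -0.11 with 3 bins, -0.17 and -0.19 unthinned, and -0.20 with few genes on the axis in the libraries labelled GFP+. That of G2/M was 0.026 with 3 bins and -0.023 unthinned in the libraries labelled RFP+, and -0.024 with few genes on the axis in those labelled GFP+. A resolution of 1.0 gave 7 clusters, one of 0.3 gave 2, and 10 and 30 components gave 4 and 3, with adjusted Rand indices to the 3 clusters described of 0.372, 0.507, 0.388 and 0.36. Without cell cycle genes 3 clusters came with an index of 0.647. Except where a reason is given, the cause was not tested. No paired analysis was possible because the replicate numbers of the labels mark lanes, which the columns merge. For the same reason lanes as samples were not run. The background genes to be set aside for counts of the lists were not defined well enough to run, and lists have no set test under the Wald test. Depth limits the shares, since a cell had a median of 1166 to 1358 counts per library.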

Other observations

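The gene groups, the length and GC offsets and the tests of explanations in this part were chosen only after the results were seen. Clustered histone genes were higher in the libraries labelled GFP+: of 16 tested, 13 rose and 1, Hist3h2a, fell, with a median log2 fold of 0.64, or 0.88 with length and GC offsets, where 14 rose and none fell. Hist1h1b, a linker histone, rose from 1347 ± 28.1 to 2216 ± 86.8 CPM (SD, n = 2). Histone genes share sequence, so single members are uncertain. Drop-seq counts polyadenylated RNA, so these values do not measure histone RNA that is not polyadenylated. A difference between library preparations cannot be told apart from one between the populations here either. Among class 3 semaphorins Sema3a and Sema3e rose, by log2 folds of 1.53 and 0.77, while Sema3c fell by 0.69 on the log2 scale. Of 10 collagen genes, 4 rose and none fell: Col1a2 (4.07), Col8a1 (2.38), Col6a1 (1.84) and Col4a5 (0.59). With the offsets, 4 rose and 1 fell. Of 6 integrin genes, Itga6 and Itgb1 rose, by 0.75 and 0.35, and Itgb4, a part of hemidesmosomes, fell by 0.92 on the log2 scale. Of 6 keratin genes, 5 fell and none rose, with a median of -1.34.

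The reporter rows were inverted against the labels in all 4 libraries, which argues against the mislabelling of 1 library. If switched cells still have higher S100a4, whose promoter drives the recombinase, and lower epithelial genes, then the log2 fold of 1.57 for S100a4 and the epithelial median of -0.98 go with exchanged names of the reporter rows and against exchanged labels of the populations. The switch is permanent, so the levels at the time of the assay need not follow it, and no value here shows that they do. Exchanged row names are thus a candidate explanation, and exchanged labels cannot be told apart from them without that premise. A biological cause was not tested.

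Libraries labelled GFP+ kept epithelial transcripts at a summed ratio of 0.529 (0.512 to 0.547 between libraries) to those labelled RFP+. Material from the other population would also carry CUSTOM_GFP, whose ratio was 0.170 (0.163 to 0.177), so it is too little to be the whole cause. A mixture of cells at the full level with cells that have none would need a shared relative variance of 0.889 across cells, and the mean in the libraries labelled GFP+ was 0.264. Per library it was 0.2775 and 0.2502 there, against 0.1472 and 0.1627 in the libraries labelled RFP+. A lower level in many cells and a less extreme mixture may both remain as explanations, and neither was tested.

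Long genes were higher in the libraries labelled GFP+, with a Spearman's rho of 0.36 across genes. With length and GC offsets the epithelial list kept a median of -0.95 and the ribosome biogenesis list one of -0.073. Their camera adjusted p values at the preset correlation were 3.66e-32 and 0.0165, which argues against the trend as the whole cause of either. Without offsets and with an estimated correlation, however, camera gave these lists adjusted p values of 0.125 and 0.235. The estimated correlations were 0.0175 and -0.00805, the latter below the preset 0.01. These adjusted p values therefore also reflect the fewer degrees of freedom of that setting. The medians of the ribosomal protein and oxidative phosphorylation lists turned to 0.086 and 0.12, so their lower level without offsets could come from the trend. With all cells thinned to 1000 counts rho was 0.33. Thinning keeps each cell's expected proportions of genes, so this value cannot decide whether the trend goes with counts per cell. A difference between library preparations cannot be told apart from one between the populations, since rho was 0.36 between them and at most 0.043 in size within them, and each library holds 1 population.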
